A study of Mus musculus with 2 samples.

How the data were processed

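Aortic cells of male Apoe-deficient mice were profiled with the 10x Genomics single cell 3' v2 chemistry, per the labels' protocols, in 1 library of 4 pooled mice for each of the control and diabetic groups. Aortae were kept on ice, minced, digested with collagenase, hyaluronidase and DNase at body temperature, filtered, pooled by group, incubated again at body temperature and sorted for cells that excluded 7AAD and took up calcein, per the labels' protocols. Digestion, incubation and sorting can set the share of each cell type and can induce immediate early and heat shock genes, and both pools went through them. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.1.0 on mm10, per the submitters' processing notes, which also name Partek without a version. The annotation release and the filter on barcodes were not given in the sources used here. The matrices were checked to hold whole numbers, and every barcode had at least 500 UMIs. A deposited table gives each annotated barcode 1 of 13 cell classes by the authors, and it covered 3060 of 4215 control and 2524 of 3458 diabetic barcodes. Annotated cells had at most 2998 genes in control and 2990 in diabetic cells and a mitochondrial share of at most 9.97% and 9.99%. Barcodes without a class were left out, including 2 diabetic barcodes listed with a blank class. Of the 1155 such control barcodes 903 lay within these limits and had at most 50% haemoglobin UMIs (median 1449 UMIs), against 9 of 934 in the diabetic library, and fixed markers assigned 152 of the 903 to erythroid cells. Genes had 18225 rows in the control and 18155 in the diabetic matrix, and of 19357 genes in either, 19124 (98.8%) were matched by symbol to the mouse annotation from which the positions were taken. The number of columns of per-sample values left unused was 0.

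UMIs were summed per library over all annotated cells and over each class with at least 50 cells in each library, which left 7 classes. The 5 with most cells were Fib-2, VSMCs-2, Mac, Fib-1 and ECs, and VSMCs-1 and Fib-3 were the further 2. Sums were scaled to CPM, and the ratio of diabetic over control was given an exact conditional binomial 95% interval. A count of 0 was set to a floor of 3 UMIs per library and class, and the ratio was then written as a bound. Shares of cells have exact Clopper-Pearson 95% intervals, and CPM values exact Poisson intervals. For 35 gene lists the median log2 ratio over members with at least 10 UMIs was set against 10000 random lists drawn within windows of 100 genes ranked by mean expression, with seed 1. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. The named genes were all 7 AP-1 subunits and, per main class and for all cells, the 5 highest and 5 lowest ratios ranked by the interval bound nearest to 1, among genes with at least 30 UMIs and at least a 1.5-fold difference, with 3 each way in the further classes. Mitochondrial, ribosomal protein and haemoglobin genes and unnamed gene models were not named by that rule. Up to 4 members that met the same size rule were named per list described, with members that went against it. Some genes that these rules name are not reported here. Groups, lists, the values and intervals compared, the naming rule, most alternatives and both tests of explanations for the AP-1 values were chosen before the data were examined. Chosen later were the rule for genes detected in many cells (a UMI in at least 10% of cells of the library with the higher level and no cell with over 10% of their UMIs in that library), a few genes added for the closing section, the other tests of explanations, which list medians count as lead results, and the alternatives named there as added.

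The lists covered AP-1 and stress responses, smooth muscle, matrix, inflammation, antigen presentation, macrophage states, lipid and glucose metabolism, organelle stress, cell cycle and endothelial genes, and marker lists of 19 cell types were summed per class to measure transcripts of other types. Alternatives were trimmed mean scaling with edgeR, scaling without mitochondrial and ribosomal protein genes, equal weight for every cell, thinning, other count minimums, a 2-fold size rule, and removal of called doublets, of the cells with most UMIs, or of the cell holding most UMIs of each gene. Doublets were called with scrublet in scanpy for each library, which called 8 of 4215 control and 20 of 3458 diabetic barcodes, far fewer than the expected rate of 0.05 set for the caller, so most doublets may have stayed in. The interval method was tested on simulated data with 200 changed genes per class. The true ratio lay inside the interval for 95.5% of 12746 genes in all annotated cells and for 96.3% of 3417 genes in Fib-1. A 2-fold change was recovered in 92.4% of changed genes in all cells, 85.5% in VSMCs-2, 82.8% in Fib-2, 78.2% in ECs, 76.8% in Mac and 63.9% in Fib-1, and a 1.5-fold change in 56.5% in Fib-2 and 30.6% in VSMCs-1. Unchanged genes were called in 0.933% of cases in all cells and 2.97% in VSMCs-1. These simulations drew the counts of each gene independently and hold counting error alone. They leave out that the UMIs of a gene can lie in few cells, so false calls in the real data can be more frequent. The spread between mice or libraries was not measured. Depth set the precision: Fib-2 held 3636171 control and 2115253 diabetic UMIs, VSMCs-2 2783387 and 5718684, Mac 2616192 and 1129707, ECs 1093038 and 853881, and Fib-1 521566 and 332209. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.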

Results

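Single-cell RNA sequencing was done on aortae of male Apoe-deficient C57BL/6 mice, an atherosclerosis-prone strain that lacks the lipoprotein ligand apolipoprotein E. Streptozotocin, a toxin that destroys insulin-producing beta cells, was injected at 55 mg/kg per day on 5 days from the age of 6 weeks, and controls received citrate vehicle. The aortae were taken at 17 weeks of age after 10 weeks of follow-up, and cells of 4 mice were pooled into 1 library per group. The series asks what the activator protein-1 (AP-1) complex, a family of Fos and Jun transcription factor dimers, does in atherosclerosis associated with diabetes. The control library held 4215 barcodes with 15314749 unique molecular identifiers (UMIs), and the diabetic library held 3458 barcodes with 17647604 UMIs. The authors gave a cell class to 3060 control cells (12390769 UMIs, median 3760 per cell) and 2524 diabetic cells (11833577 UMIs, median 4477.5 per cell). With 1 library per group no difference has a replicate check, so no p-value is given, and all 95% intervals cover counting error only. A gene is called higher or lower in the diabetic library where its CPM, the UMIs of the gene scaled to the total UMIs of the cells compared, differed at least 1.5-fold and the interval of the ratio excluded 1. Ratios are diabetic over control throughout.

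Apoe, which is knocked out in both groups and therefore checks no contrast, had 48 UMIs in annotated control cells (3.87 CPM, interval 2.86 to 5.14) and 63 in annotated diabetic cells (5.32 CPM, 4.09 to 6.81). Haemoglobin transcripts, which come from red cells, made up 0.217% of UMIs in annotated control cells and 1.14% in annotated diabetic cells. The median share per annotated cell was 0% and 0.0749%, and 3 control and 14 diabetic annotated cells had over 50% haemoglobin UMIs. Haemoglobin and erythroid sums of a class can therefore rest on few cells. The median mitochondrial share of UMIs was 2.87% in control and 3.83% in diabetic cells, and the median ribosomal protein share was 13.9% and 16.0%. Of the barcodes without a class, 29 in the control and 487 in the diabetic library had over 50% haemoglobin UMIs, and 150 and 324 others had over 10% mitochondrial UMIs.

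The first comparison asked how the cellular make-up of the aorta differed between both libraries. Smooth muscle cells, the contractile cells of the vessel wall, made up a larger share of the diabetic library, and fibroblasts and macrophages a smaller one. The main smooth muscle class, VSMCs-2, held 16.2% of annotated control cells (14.9 to 17.6%) and 33.9% of annotated diabetic cells (32.1 to 35.8%). Both smooth muscle classes together rose from 20.6% to 40.2%, a difference of 19.6 percentage points (17.2 to 22.03). The 3 fibroblast classes together went from 46.1% to 33.5%, a difference of -12.6 points (-15.2 to -10.0), and the largest of them, Fib-2, from 29.6% (28.0 to 31.3%) to 21.1% (19.5 to 22.8%). The macrophage class, Mac, went from 16.7% (15.4 to 18.0%) to 9.07% (7.98 to 10.3%), and all myeloid classes together differed by -7.30 points (-9.19 to -5.39). Lymphoid classes went from 2.39% to 5.59%, a difference of 3.20 points (2.15 to 4.30), with 13 T cells in the control and 60 in the diabetic library. Of these T cells, 10 of 13 control and 57 of 60 diabetic cells had a UMI of a gene of developing T cells. Whether they came from the aortic wall was not tested. Endothelial cells (ECs), which line the vessel, went from 12.0% to 9.03%, a difference of -2.93 points (-4.55 to -1.29). That endothelial difference shrank to -0.732 points (-2.13 to 0.704) when all cells were assigned by the fixed markers and barcodes without a class that lay within the quality limits were added, 903 of them in the control and 9 in the diabetic library. Assignment by the fixed markers alone gave -3.35 points. Cells were sorted for viability and calcein after digestion, so shares describe the sorted suspension.

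**Figure D1:**
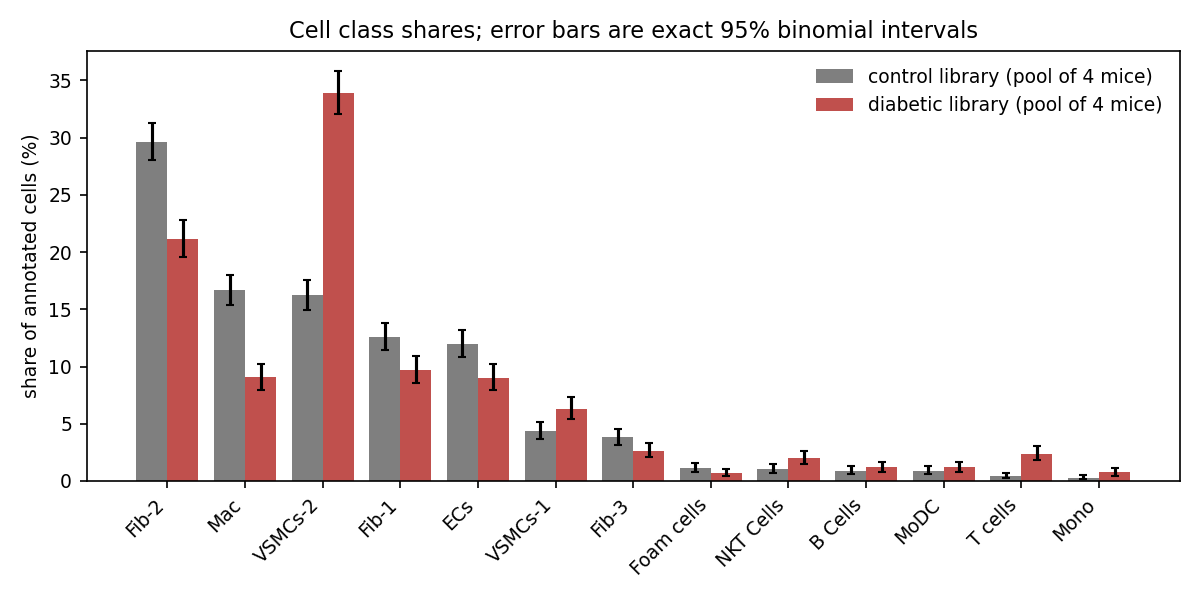
Share of annotated cells in percent (vertical axis) for each deposited cell class in the control and the diabetic library, 1 pool of 4 mice each. Bars are shares and error bars are exact 95% binomial intervals, and VSMCs-2 stood at 16.2% in control and 33.9% in diabetic cells while Fib-2 stood at 29.6% and 21.1%.

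The second comparison asked whether transcripts of the AP-1 subunits differed between both libraries within each cell class. Junb, a Jun-family subunit, had a ratio above 1 with an interval excluding 1 in each of the 7 classes compared, and was called higher in ECs, VSMCs-1 and Fib-2. Junb was 2.06-fold higher in ECs (1.85 to 2.29), 1.69-fold in VSMCs-1 (1.22 to 2.37) and 1.56-fold in Fib-2 (1.48 to 1.64). The ratio of Junb was 1.38 in VSMCs-2 (1.29 to 1.48), 1.32 in Fib-1 (1.16 to 1.49), 1.29 in Fib-3 (1.12 to 1.49) and 1.26 in Mac (1.15 to 1.38). Jund was higher 1.92-fold in VSMCs-2 (1.66 to 2.23), 1.58-fold in Mac (1.38 to 1.81) and 1.57-fold in Fib-2 (1.37 to 1.80). Fosl2, a Fos-family subunit, was higher 2.24-fold in Fib-1 (1.43 to 3.56), 1.73-fold in Fib-2 (1.43 to 2.10) and 1.65-fold in ECs (1.08 to 2.55), and its ratio in VSMCs-1 was 0.477 with an interval that held 1 (0.182 to 1.18). Fosb was higher 1.66-fold in ECs (1.496 to 1.85) and 1.80-fold in VSMCs-1 (1.29 to 2.55), Jun 1.65-fold in Fib-3 (1.28 to 2.12), and Fosl1 1.59-fold in Fib-3 (1.04 to 2.43). Fos, the most abundant subunit in all cells together, was called in none of the 7 classes compared: its ratio was 0.911 in Fib-2 (0.887 to 0.936), 0.878 in VSMCs-2 (0.860 to 0.896), 0.789 in Fib-1 (0.730 to 0.853), 1.13 in ECs (1.08 to 1.18), 1.31 in Mac (1.19 to 1.44) and 1.32 in Fib-3 (1.19 to 1.47). No AP-1 subunit was called lower in these 7 classes, and none was called in all annotated cells pooled, where Junb had a ratio of 1.28 (1.24 to 1.32) and Jund of 1.33.

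As a list, the AP-1 subunits stood highest in ECs, with a median log2 ratio of 0.73 and 3 of 7 members higher. The percentile of that median among 10000 random lists of the same size and similar expression was 99.99, given here and for all lists as a description of these libraries. The median was 0.55 in VSMCs-1 (percentile 99.8, 2 of 6 members higher), 0.42 in Fib-2 (99.8, 3 of 7), 0.41 in Fib-3 (99.8, 2 of 7), 0.34 in Fib-1 (99.7, 1 of 6), 0.33 in Mac (98.9, 1 of 7) and 0.20 in VSMCs-2 (96.9, 1 of 7). In all annotated cells together it was 0.17 (85.0). With the ATF, BATF, JDP and MAF partners added to the list, the median was 0.02 in all cells, 0.10 in Mac, 0.13 in VSMCs-2 and 0.26 in Fib-3. With every cell weighted equally it was 0.05 in Mac and 0.21 in VSMCs-1, and with cells thinned to 1000 UMIs it was 0.22 in Mac and 0.64 in Fib-2. Scaling the Mac class by trimmed means, which shifted every log2 ratio there by -0.12, gave 0.21. With that shift Jund, the only member called in Mac, fell below the 1.5-fold size rule. Other immediate early genes, which respond to many stimuli and to tissue digestion, had medians of 0.55 in ECs, 0.39 in Fib-2, 0.15 in Mac, 0.14 in Fib-1, 0.09 in VSMCs-2, 0.06 in VSMCs-1 and 0.04 in Fib-3. Heat shock genes had medians of -0.59 in VSMCs-1, -0.46 in VSMCs-2, -0.24 in Fib-3, -0.22 in ECs, -0.09 in Fib-2, 0.04 in Fib-1 and 0.19 in Mac.

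**Figure D2:**
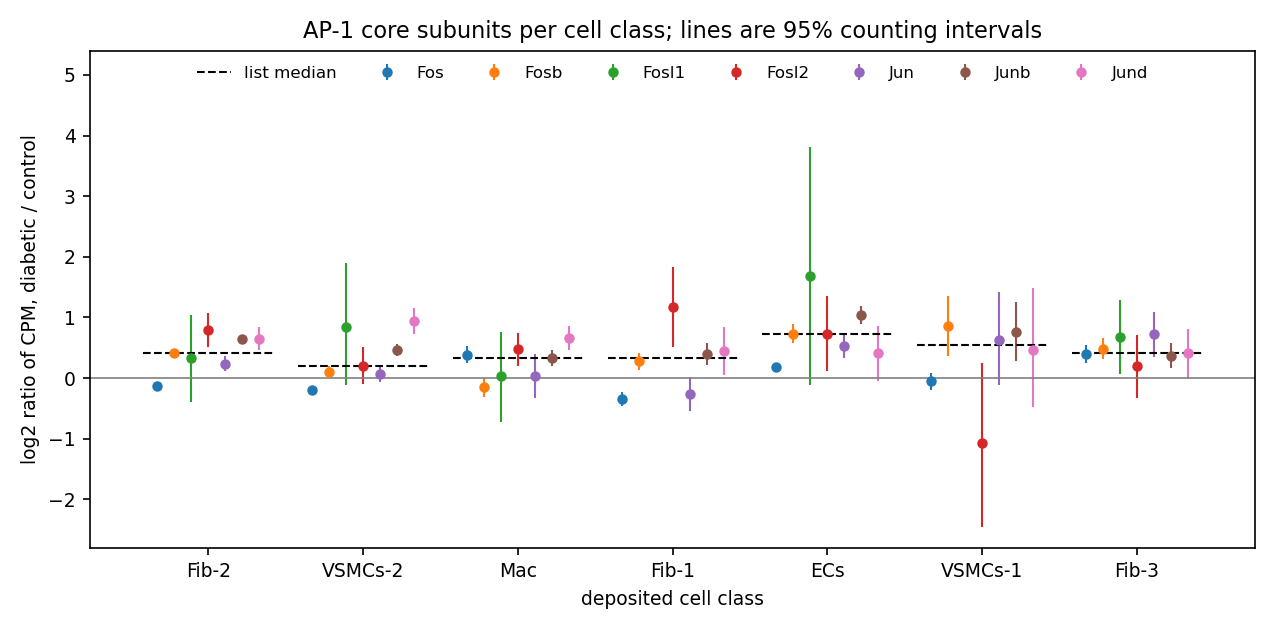
Log2 ratio of CPM, diabetic over control (vertical axis), for the 7 AP-1 subunits in each of the 7 cell classes compared, 1 library per group. Points are ratios, lines are 95% counting intervals and dashes are list medians, which ranged from 0.20 in VSMCs-2 to 0.73 in ECs.

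Summed over all subunits, AP-1 transcripts went from 5402 to 7028 CPM in ECs, a ratio of 1.30 (1.25 to 1.35), and from 6461 to 6147 CPM in VSMCs-2, a ratio of 0.951 (0.934 to 0.969). The ratio of the sum was 1.35 in Fib-3 (1.27 to 1.44), 1.21 in Mac, 1.09 in Fib-2 (1.07 to 1.12), 1.06 in VSMCs-1 and 1.00 in Fib-1. Fos made up most of the sum in VSMCs-2 (5043 CPM in control and 4426 CPM in diabetic cells), Fib-2 (4239 and 3861 CPM) and ECs (3876 and 4381 CPM), but not in Mac (461 and 603 CPM). Of all deposited classes, Fib-1 had the highest AP-1 sum in control (7401 CPM) and T cells the lowest (166 CPM, from 8 UMIs). In the diabetic library the sum was 7414 CPM in Fib-1, 7423 CPM in Fib-2 and 283 CPM in T cells. The share of cells with a Junb UMI, after each cell was thinned to 1000 UMIs, was 24.5% in control ECs (20.03 to 29.4%) and 46.4% in diabetic ECs (39.6 to 53.2%), with 23 and 8 shallower ECs left out. It was 40.6% and 52.7% in Fib-2, 27.4% and 34.5% in VSMCs-2, and 48.4% and 52.3% in Fib-1. Fib-1 held cells of under 1000 UMIs, down to 501 in control and 506 in diabetic cells, so its shares describe its deeper cells. In Mac the share with a Junb UMI was 32.2% in both, a difference of -0.0324 points that was 14.6 points at 2000 UMIs, so no order was read from it. Without thinning, at median depths of 2867 and 3504 UMIs per EC, the shares were 41.5% and 67.5%. No class is known to lack Junb, and its lowest level was in T cells. It was 20.8 CPM in control T cells (0.527 to 116, from 1 UMI) and 103 CPM in diabetic T cells (62.9 to 159, from 20 UMIs). These intervals overlap, so no order was read from them.

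On the mm10 assembly (GRCm38) the annotated genes lie on chromosome 12 from 85473890 to 85477273 (Fos), chromosome 7 from 19302696 to 19310051 (Fosb), chromosome 19 from 5447547 to 5455946 (Fosl1) and chromosome 5 from 32135801 to 32157842 (Fosl2). The Jun family genes lie on chromosome 4 from 95049034 to 95052222 (Jun) and on chromosome 8 from 84974484 to 84978718 (Junb) and from 70698949 to 70700616 (Jund). Values are gene-level counts from the 3' ends of transcripts and do not separate isoforms.

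The third comparison asked which other gene groups differed in VSMCs-2, with 496 control and 856 diabetic cells. Genes of cholesterol synthesis and uptake were higher in diabetic VSMCs-2 cells, and genes of chaperones and of the modulated, matrix-producing smooth muscle state were lower. Of 24 measured cholesterol genes, 12 were higher and 0 lower (median log2 ratio 0.66, percentile 100). They included the sterol synthesis gene Hsd17b7 at 2.64-fold (1.17 to 7.01) and the squalene epoxidase Sqle at 2.21-fold (1.55 to 3.21). Heat shock genes had a median of -0.46 (percentile 0.00) with 4 of 15 lower: the mitochondrial chaperonin Hspd1 had a ratio of 0.577 (0.515 to 0.646), the cytosolic chaperone Hspa8 of 0.593 (0.578 to 0.608), Hsp90aa1 of 0.621 and Hsph1 of 0.657. Endoplasmic reticulum stress genes had a median of -0.35 with 6 of 21 lower, among them the luminal chaperone Hspa5 at 0.520 (0.493 to 0.547), Sdf2l1 at 0.396 and the disulfide isomerases Pdia6 at 0.523 and Pdia4 at 0.596. Contractile genes were mixed (median 0.06, percentile 76.0): the enteric actin Actg2 at 1.62-fold and desmin (Des) at 1.55-fold were higher, Sncg at 0.547 and phospholamban (Pln) at 0.593 were lower, and smooth muscle actin (Acta2) had a ratio of 0.955. At a 2-fold size rule 4 cholesterol genes were higher and 0 heat shock genes lower.

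Modulated smooth muscle genes had a median of -0.90 in VSMCs-2 with 14 of 25 lower. Single control cells held much of the largest differences. Chad, a cartilage matrix gene, had a ratio of 0.00492 with 97.98% of its control UMIs in 1 cell, and Prg4, a lubricin gene, of 0.0624 with 97.4% in 1 cell. Spp1, the matrix phosphoprotein osteopontin, had a ratio of 0.0202 (0.0106 to 0.0351) with 65.2% in 1 cell, and Cytl1 of 0.119 (0.0942 to 0.149) with 32.8% in 1 cell. Cytl1 was also among the top genes of ECs, at 11529.5 CPM against a mean of 223.6 CPM in the other classes. Fn1, fibronectin, went against the list with a ratio of 1.29, below the size called. Markers of other cell types moved with these groups in VSMCs-2: the macrophage marker sum had a log2 ratio of -2.16 (451 UMIs in control, 207 in diabetic), the fibroblast marker sum of -1.07, the pericyte marker sum of 0.90, the adipocyte marker sum of 2.68 (5 and 66 UMIs) and the erythroid marker sum of 6.64, while the smooth muscle marker sum stood at -0.03. The pericyte sum was mostly Rgs5, with 2575 of 3397 UMIs in control and 11079 of 12982 in diabetic cells. Rgs5 was also among the top genes of VSMCs-2, so that sum need not reflect another cell type. The class II antigen presentation list, which mainly antigen-presenting cells express, had a median of -2.21 (5 of 7 lower), and of -1.48 over members with at least 1 UMI. The complement list, which holds genes abundant in macrophages and genes abundant in fibroblasts, such as C3 and Serping1, had a median of -1.17 (9 of 14 lower). AP-1 target genes had a median of -0.39 with 9 of 20 lower and 1 higher, the chemokine Cxcl1 at 1.54-fold, and the median was -0.23 over members with at least 30 UMIs. That list shares Spp1, Vcam1, Timp1 and Fn1 with the modulated smooth muscle list, so both medians are not independent. Of these Spp1, Vcam1 at 0.294 and Timp1 at 0.644 were lower, and Fn1 was not called.

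By the fixed size rule the genes highest in diabetic VSMCs-2 cells included Alas2 (at least 37.2-fold), Cfd (at least 13.1-fold), Car3 (20.9-fold) and Hist1h1c (3.31-fold, 2.80 to 3.94). Alas2, a haem synthesis enzyme, is abundant in erythroid cells, and Cfd and Car3 are adipocyte genes whose diabetic UMIs lay to 93.8% and 95.4% in 1 cell. Hist1h1c, a linker histone, was spread over 111 of 496 control and 420 of 856 diabetic cells. The lowest were Col2a1, Hp, Chad, Bpifb1 and Spp1, and 1 cell held 97.8% of the control UMIs of the cartilage collagen Col2a1, 89.8% of haptoglobin (Hp) and 100% of Bpifb1. Among genes detected in many cells, a rule added after the values were seen, the G protein regulator Rgs5 was 2.09-fold higher (2.01 to 2.19), the small GTPase Rrad 2.15-fold, the cold-inducible RNA binding gene Cirbp 2.07-fold and desmoplakin (Dsp) 2.20-fold. Serpinf1 at 0.245 and Pcolce at 0.418, both abundant in fibroblasts, and the macrophage gene Lyz2 at 0.219 were lower. Of the 10 genes named by the fixed rule, 6 kept a 1.5-fold difference on their side without the cell holding most UMIs.

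**Figure D3:**
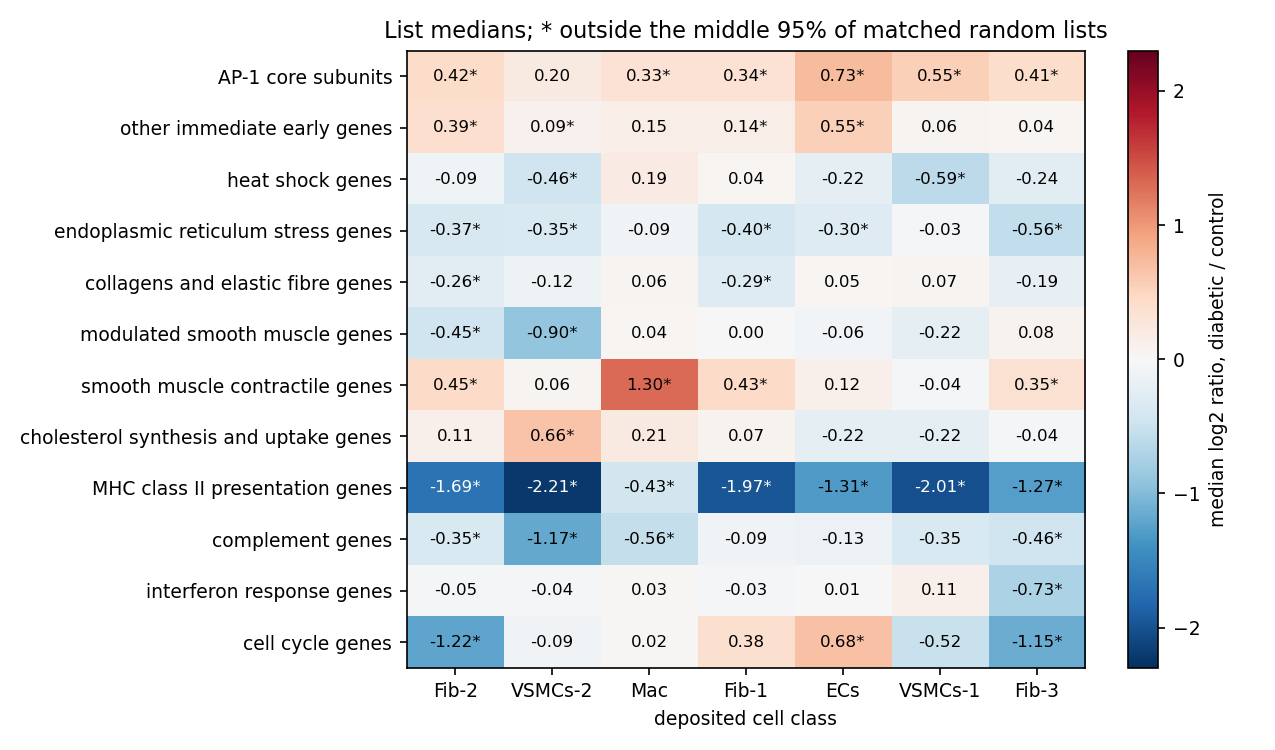
Median log2 ratio of CPM, diabetic over control (colour), for 12 gene lists (vertical axis) in the 7 cell classes compared (horizontal axis), 1 library per group. Numbers are medians and an asterisk marks a median outside the middle 95% of 10000 matched random lists, as for cholesterol genes at 0.66 in VSMCs-2.

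The fourth comparison was that of Fib-2, the largest fibroblast class, with 907 control and 533 diabetic cells. Immediate early genes were higher in diabetic Fib-2 cells, and collagen, matrix and endoplasmic reticulum chaperone genes were lower. Of 34 immediate early genes 7 were higher (median 0.39, percentile 100), among them the orphan nuclear receptor Nr4a3 at 2.05-fold (1.61 to 2.63), Csrnp1 at 1.93-fold, Ier5 at 1.91-fold and Ier2 at 1.77-fold. Of 28 collagen and elastic fibre genes 7 were lower (median -0.26, percentile 0.0100): the crosslinking enzyme Loxl2 had a ratio of 0.443 (0.320 to 0.603), the fibrillar collagens Col3a1 of 0.579 (0.560 to 0.598) and Col1a1 of 0.622, and Mfap4 of 0.601, while elastin (Eln) had a ratio of 1.29. Of 33 other matrix genes 9 were lower (median -0.25), with tenascin C (Tnc) at 0.330, thrombospondin 1 (Thbs1) at 0.453, Fn1 at 0.474 and Sparc, a collagen-binding glycoprotein, at 0.504 (0.495 to 0.514). The aggrecan-cleaving proteases Adamts4 at 2.05-fold and Adamts1 at 1.52-fold went against that list. Endoplasmic reticulum stress genes had a median of -0.37 with 6 of 21 lower, including Creld2 at 0.396, Pdia4 at 0.447, Pdia6 at 0.479 and Hspa5 at 0.485 (0.462 to 0.508), and the pseudokinase Trib3 went against them at 2.29-fold. Among antioxidant genes (median 0.20, percentile 98.5) the metallothioneins Mt2 at 1.93-fold and Mt1 at 1.79-fold and the extracellular superoxide dismutase Sod3 at 1.65-fold were higher. At a 2-fold size rule 1 immediate early gene was higher and 1 collagen or elastic fibre gene lower.

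Cell cycle genes had a median of -1.22 in Fib-2 with 9 of 20 lower, including Cdc20 at 0.172 and Ube2c at 0.264, and that median was -0.16 without the cell holding most UMIs of each gene and -0.30 over members with at least 30 UMIs. Chemokines and cytokines were mixed in Fib-2, with 6 lower and 3 higher, the latter Ccl7 at 1.78-fold, Il6 at 1.74-fold and Ccl19 at 1.52-fold. Their median of -0.23 was -0.13 without the top cell of each gene and -0.02 over members with at least 30 UMIs. Beside all these groups, the macrophage marker sum in Fib-2 had a log2 ratio of -2.26 (963 UMIs in control, 117 in diabetic), the erythroid sum of 5.85 (505 and 16908), the neutrophil sum of -3.09 (117 and 8), the mesothelial sum of -1.66 (287 and 53), the fibroblast sum of -0.39 and the smooth muscle sum of 0.58. The class II antigen presentation list, a macrophage and dendritic cell product, had a median of -1.69. By the fixed rule the highest genes were the acute phase gene Saa3 (69.3-fold, 36.1 to 153, with 56.8% of diabetic UMIs in 1 cell), Alas2 (40.7-fold, 50.7%), the collagenase Mmp13 (18.0-fold, 95.2%), the protease inhibitor Slpi (8.60-fold, 92.3%) and Coch (7.45-fold, 30.8%). Without that cell the log2 ratio of Slpi was 0.12. The lowest were Col2a1 (0.0115, in 11 of 907 control cells), the bone matrix gene Ibsp (0.0108, 60.4% in 1 control cell), Bpifb1 (70.3%), Saa1 (86.3%) and lipocalin 2 (Lcn2, 0.0658, 26.8%). Without those cells the log2 ratio of Saa1 was -0.42. Of genes detected in many cells, the collectin Colec11 was 4.28-fold higher, Cirbp 2.66-fold (2.23 to 3.18), the retinol carrier Rbp4 2.54-fold (2.39 to 2.71) and the transcription factor Osr1 2.31-fold. Tsc22d3, a glucocorticoid-induced gene, at 0.382 (0.339 to 0.430) and the collagen chaperone Serpinh1 at 0.496 were lower.

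The fifth comparison was that of Mac, with 510 control and 229 diabetic cells. Complement genes and genes of resident macrophages were lower in diabetic Mac cells, and the foamy macrophage and chemokine lists held members in both directions. Of 16 complement genes 7 were lower (median -0.56, percentile 0.00), including C2 at 0.416, the anaphylatoxin receptors C5ar1 at 0.459 and C3ar1 at 0.587 and the recognition subunit C1qa at 0.542, and C3 went against them at 2.17-fold. Of 17 resident macrophage genes 6 were lower (median -0.45, percentile 0.0450): the lectin Mgl2 had a ratio of 0.409 (0.365 to 0.457), the leukotriene synthase Ltc4s of 0.425, the phosphatidylserine receptor Timd4 of 0.449 and the hyaluronan receptor Lyve1 of 0.535. The foamy macrophage list was split, with 7 of 27 members higher and 6 lower. The glycoprotein Gpnmb at 6.44-fold, Spp1 at 4.83-fold (4.09 to 5.72, 34.6% of diabetic UMIs in 1 cell), the fatty acid binding gene Fabp5 at 4.59-fold and Cd5l at 3.40-fold were higher, and the lysosomal genes Hexa at 0.619, Cd68 at 0.646 and Ctsb at 0.653 and the lipid carrier gene Fabp4 at 0.655 were lower. Its median was -0.22, and 0.07 with every cell weighted equally. Inflammatory monocyte genes had a median of 0.36 with 6 of 20 higher and 3 lower, higher being the clotting factor F10 at 4.63-fold, Fn1 at 2.12-fold, the chemokine receptor Ccr2 at 2.06-fold and Plac8 at 1.66-fold, and lower the chemokines Ccl4 at 0.573, Cxcl2 at 0.634 and Ccl3 at 0.666. That median was 0.04 in the cells that the fixed markers assigned to macrophages, 489 of 510 and 189 of 229.

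Among chemokines and cytokines in Mac (median -0.22, -0.12 without mitochondrial and ribosomal protein genes, -0.36 without called doublets and -0.38 in marker-assigned macrophages), 10 were lower, including Cxcl12 at 0.207, Cxcl1 at 0.426 and the cytokine Il10 at 0.488, and 4 were higher: Cxcl13 at 8.23-fold, Ccl8 at 2.44-fold (2.27 to 2.63), Il6 at 2.32-fold and Il1b at 1.65-fold. Beside these groups, the smooth muscle marker sum in Mac had a log2 ratio of 1.55 (795 UMIs in control, 1002 in diabetic), the dendritic sum of 1.30 (322 and 342), the mast cell sum of 2.71 (17 and 48) and the T cell sum of 1.04. The lymphatic endothelial sum, which holds Lyve1, had a log2 ratio of -0.80 there, the natural killer sum of -1.47, the B cell sum of -0.60, the neutrophil sum of 0.51 and the macrophage sum of -0.67. Contractile genes, which macrophages should lack, had a median of 1.30 with 15 of 18 higher, of 0.88 without called doublets and of 0.59 in the marker-assigned macrophages. At a 2-fold size rule 2 complement and 3 resident macrophage genes were lower, and of the inflammatory monocyte genes 3 were higher and 0 lower. By the fixed rule the highest genes were the chemokine Ccl17 (153-fold, 51.5 to 747, in 10 of 229 diabetic cells), arginase 1 (Arg1, 192-fold, 33.6 to 7682, in 9 diabetic cells), Ccl22 (15.3-fold, 81.8% of diabetic UMIs in 1 cell), the muscle gene Mustn1 (7.35-fold) and Spp1. Arg1 had 1 UMI in control and 83 in diabetic Mac cells, 28.9% of the latter in 1 cell. The lowest included the neutrophil granule genes Camp, Ngp and Ltf with 99.8%, 99.7% and 100% of control UMIs in 1 cell, and the lipopolysaccharide co-receptor Cd14 at 0.382 (0.356 to 0.410), detected in 476 of 510 control and 164 of 229 diabetic cells. Of genes detected in many cells, the lymphocyte genes Rag1 at 4.85-fold (2.82 to 8.59), Myb at 4.70-fold, Bcl11b at 3.94-fold and Trbc1 at 2.25-fold were higher, with their source not settled between macrophages, doublets and engulfed cells, and Cd81 at 0.483 was lower.

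The sixth comparison was that of ECs, with 366 control and 228 diabetic cells. Immediate early genes were higher in diabetic ECs, 13 of 35 of them (median 0.55, percentile 100), and endoplasmic reticulum chaperones were lower. Ier2 was 2.41-fold higher (2.01 to 2.88), the NF-kappaB regulator Nfkbiz 2.14-fold, Csrnp1 2.11-fold and the pseudokinase Trib1 2.05-fold. Of 21 endoplasmic reticulum stress genes 8 were lower (median -0.30, percentile 0.200), including Creld2 at 0.469, Pdia4 at 0.492, Sdf2l1 at 0.546 and Trib3 at 0.549. Interferon response genes had a median of 0.01 (percentile 72.6), yet 6 of 34 were higher, among them the antiviral gene Rsad2 at 7.17-fold, the transcription factor Irf7 at 3.74-fold (2.37 to 6.09), the nucleic acid sensor Zbp1 at 2.44-fold and Ifi27l2a at 1.93-fold. Endothelial identity genes had a median of 0.05, and the vascular endothelial growth factor receptor Kdr was 1.81-fold higher. AP-1 target genes had a median of 0.24 in ECs, with a counting interval that held 0 (-0.06 to 0.43). Cell cycle genes had a median of 0.68 with 5 of 12 higher, including Cks2 at 2.08-fold, Hmgb2 at 1.66-fold and Stmn1 at 1.65-fold, and that median was 0.27 with every cell weighted equally or without the top cell of each gene. At a 2-fold size rule 7 immediate early and 3 cell cycle genes were higher and 3 endoplasmic reticulum stress genes lower. Beside these groups the lymphatic endothelial marker sum in ECs had a log2 ratio of 1.05 (442 UMIs in control, 717 in diabetic), the monocyte sum of 2.21 (18 and 65), the neutrophil sum of 4.81 (11 and 241), the adipocyte sum of 5.401 (2 and 66), the platelet sum, which holds Pf4, of -2.94, the fibroblast sum of -0.41, the macrophage sum of -0.89 and the blood endothelial sum of -0.07. Of the 241 diabetic UMIs in the neutrophil sum, 130 were S100a8 UMIs of 1 cell and 92 were S100a9 UMIs of 1 cell. In addition, 6 of 7 class II antigen presentation genes were lower, including Cd74 at 0.273. By the fixed rule the highest genes included S100a8, S100a9, Car3 and Cfd. The neutrophil genes S100a8 (28.4-fold, 97.7% of diabetic UMIs in 1 cell) and S100a9 (23.6-fold) both had too few UMIs left to read a direction without the cell holding most UMIs in each library. The lowest were the macrophage genes C1qc at 0.0784, C1qa at 0.105 and C1qb at 0.113, the natriuretic peptide gene Nppc at 0.0441 (9 of 366 control cells and 1 of 228 diabetic cells) and Pf4 at 0.126. Of genes detected in many cells, Cirbp was 2.56-fold higher, Ier3 1.91-fold and the cold-inducible gene Rbm3 1.87-fold, and Tsc22d3 at 0.356 (0.294 to 0.429) and the kallikrein Klk10 at 0.508 were lower.

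**Figure D4:**
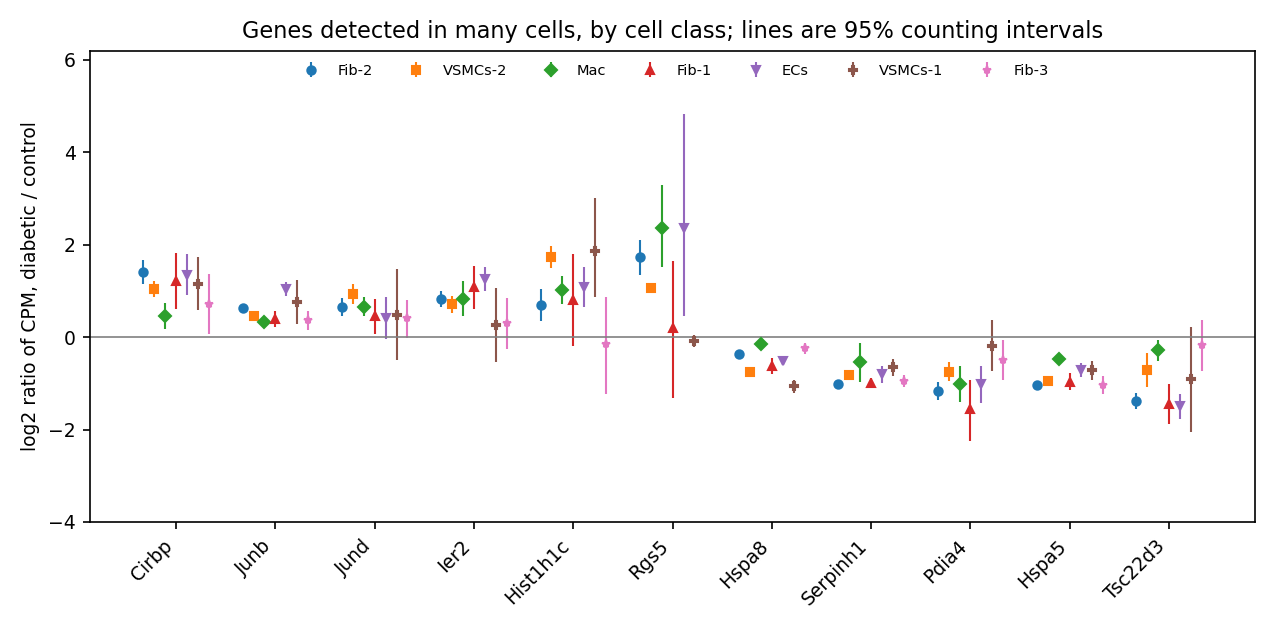
Log2 ratio of CPM, diabetic over control (vertical axis), with 95% counting intervals, for genes detected in many cells (chosen after their values were seen) in the 7 cell classes compared, 1 library per group. Points are ratios, and Cirbp lay above 0 in each class while Tsc22d3 lay below 0 in each, with intervals that held 0 in VSMCs-1 and Fib-3.

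The seventh comparison was that of Fib-1, a fibroblast class of shallow cells (median 1410 UMIs in control and 1240 in diabetic cells). Endoplasmic reticulum stress genes were lower in diabetic Fib-1 cells, 6 of 19 of them (median -0.40, percentile 0.155), with Pdia4 at 0.341, Manf at 0.402, Creld2 at 0.502 and Hspa5 at 0.514, and 2 were lower at a 2-fold size rule. Collagen and elastic fibre genes had a median of -0.29, and of -0.16 with every cell weighted equally. Within that list Col15a1 at 0.415, Emilin1 at 0.523, Col5a2 at 0.630 and Col3a1 at 0.638 were lower, and the elastic fibre genes Eln at 1.85-fold and Fbln5 at 1.55-fold were higher. AP-1 target genes had a median of 0.24 (percentile 99.6), and of 0.14 without the top cell of each gene. Higher members included Nfatc1 at 2.51-fold, Spp1 at 2.39-fold (84.4% of diabetic UMIs in 1 cell) and the chemokine Ccl2 at 2.22-fold, and lower were the matrix proteases Mmp3 at 0.594 and Mmp2 at 0.662. Heat shock genes went both ways, with the inducible Hspa1a at 2.35-fold and Dnajb1 at 1.92-fold higher, and Hspd1 at 0.438 and Hspa8 at 0.651 lower. By the fixed rule the highest genes included the erythroid genes Alas2 (22.4-fold) and Bpgm (9.11-fold), the retinol carrier Rbp4 (2.62-fold, 2.24 to 3.08) and Hspa1a. The lowest were the macrophage-rich transcripts H2-Ab1 at 0.0981, C1qc at 0.127, Pf4 at 0.187 and Cd74 at 0.289, and Chad at 0.139 with 97.1% of control UMIs in 1 cell. The haemoglobin share of summed UMIs in Fib-1 was 0.252% in control and 4.61% in diabetic cells, while the median share per cell was 0% and 0.172%. Beside these groups the macrophage marker sum had a log2 ratio of -1.25, the smooth muscle sum of 0.56, the fibroblast sum of -0.13 and the erythroid sum of 4.19.

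In VSMCs-1, the smaller smooth muscle class with 134 control and 159 diabetic cells, heat shock genes were lower, 7 of 15 of them (median -0.59), with the small chaperone Hspb1 at 0.386, Hspa8 at 0.479 (0.436 to 0.527), Hsph1 at 0.483 and Dnajb1 at 0.512. AP-1 target genes had a median of -0.56 there, and of -0.97 with every cell weighted equally, with Spp1 at 0.0640 (87.9% of control UMIs in 1 cell) and the adhesion molecule Vcam1 at 0.371 among those lower. Beside both groups the macrophage marker sum in VSMCs-1 had a log2 ratio of -1.92 (76 UMIs in control, 27 in diabetic), the fibroblast sum of -1.02, the adipocyte sum of -0.95, the erythroid sum of 0.97 and the smooth muscle sum of -0.15. The named highest genes in VSMCs-1 were Tmtc2 at 4.90-fold, Hist1h1c at 3.64-fold and Coch at 3.51-fold, and the lowest were Cytl1 at 0.0571 (87.2% in 1 control cell), Spp1, and lumican (Lum) at 0.0953 (70.6%). In Fib-3, with 117 control and 67 diabetic cells, 9 of 21 endoplasmic reticulum stress genes were lower (median -0.56), including Hspa5 at 0.488, Pdia6 at 0.495, Sel1l at 0.506 and Sdf2l1 at 0.514. Interferon response genes had a median of -0.73 in Fib-3 with 3 of 23 lower, Ifi203 at 0.422, Ifi35 at 0.436 and Bst2 at 0.460, and the median was -0.15 over members with at least 30 UMIs. Chemokines in Fib-3 included Ccl19 at 6.32-fold, Cxcl16 at 2.15-fold and Cxcl12 at 2.05-fold, which were higher, and Pf4 at 0.181 and the eotaxin Ccl11 at 0.663, which were lower. Beside these groups the macrophage marker sum in Fib-3 had a log2 ratio of -3.49 (244 UMIs in control, 12 in diabetic), the erythroid sum of 7.50 (81 and 8136), the pericyte sum of 1.48, the smooth muscle sum of 0.73 and the fibroblast sum of -0.36. The named highest genes in Fib-3 were Dlk1, Alas2 and Saa3, whose diabetic UMIs came from 1 cell each. The lowest were the macrophage genes C1qa at 0.0354 (51.0% of control UMIs in 1 cell), Lyz2 at 0.0911 (53.8%) and C1qc (69.8%).

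In all annotated cells together the values mix class shares with levels within classes, and the part of each was not computed. Of 23 contractile genes 21 were higher (median 1.07), of 18 complement genes 16 were lower (median -1.18) and of 17 resident macrophage genes 13 were lower (median -1.19). Smooth muscle genes detected in many cells were higher, with Rgs5 at 3.73-fold, Actg2 at 3.09-fold, Des at 2.88-fold and Myh11 at 2.63-fold, and Cd14 at 0.219, C5ar1 at 0.212 and Mgl2 at 0.211 were lower. By the fixed rule the highest genes included Saa3 (27.9-fold, 48.2% of diabetic UMIs in 1 cell), Dlk1 (at least 15.0-fold, all in 1 cell), Arg1 (9.04-fold) and Alas2 (5.16-fold). The lowest were Camp (98.3% of control UMIs in 1 cell), Ngp (0.00493, 99.2%), the plasma cell genes Igha (0.00276, 97.9%) and Jchain (0.00327, 98.7%), and Col2a1 (0.00592). These figures describe both libraries and carry the class shares, so the values within classes are the ones set side by side above.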

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

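Both tests of the AP-1 pattern were planned ahead, and the tests of the modulated smooth muscle pattern and of the chaperone pattern were chosen only after the result was seen.

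The Fos ratio stood on opposite sides of 1 in VSMCs-2 (0.878) and in ECs (1.13), and the difference was not tested. The Spp1 ratio stood at 0.0202 in VSMCs-2 and at 4.83 in Mac, again on opposite sides of 1, and the difference was not tested. Barcodes outside the annotated cells held 487 with over 50% haemoglobin UMIs in the diabetic library against 29 in the control library, and the difference was not tested. They also held 324 with over 10% mitochondrial UMIs in the diabetic library against 150 in the control library, and the difference was not tested.

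AP-1 subunit medians were above 0 in each of the 7 classes, highest in ECs at 0.73. After thinning, 6 of the 7 classes kept over 75% of the median, the exception being Mac at 66.4%. That test cannot decide on a difference in depth per cell. CPM is scaled to total UMIs, and thinning leaves the expected share of a gene within each cell unchanged. Stress during dissociation or sorting stays open: in 0 of the 7 classes did other immediate early genes and heat shock genes both reach 50% of the AP-1 median, but immediate early genes alone did in ECs and Fib-2 and heat shock genes alone in Mac, and both lay below 25% of it in VSMCs-1 and Fib-3 alone. With 1 pool per group, handling and diabetes cannot be told apart for these genes. An effect of diabetes on AP-1 transcription stays open and was not tested.

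Modulated smooth muscle genes were lower in diabetic VSMCs-2 cells, with a list median of -0.90. Single control cells carried most UMIs of Chad and Prg4, but without the cell holding most UMIs of each gene the median was -0.87, which argues against single cells as the whole cause. Free RNA of fibroblasts and macrophages, whose cells made up a larger share of the control library, was not measured itself and stays open: 4 members at a level of their own in VSMCs-2 had a median of -0.43 (-0.69 to -0.24), and the other 21 members -1.16. The value for those 4 lies between what free RNA alone and no free RNA would give, so both cannot be told apart. Levels were compared with the fibroblast classes and Mac only, so free RNA of ECs was not weighed. A lower share of modulated cells with diabetes may also contribute and was not tested.

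The median of the endoplasmic reticulum stress genes was below 0 in each of the 7 classes, and that of heat shock genes in each but Mac and Fib-1 (0.09 in all cells), while the ratios of the cold-inducible genes Cirbp and Rbm3 were above 1 in each. Scaling by haemoglobin, mitochondrial and ribosomal protein UMIs is argued against as the whole cause for the endoplasmic reticulum genes alone, because 4 of the 7 classes kept over 75% of their median without those genes (Fib-1 kept 74.8%, and the medians of Mac and VSMCs-1, near 0 before, turned to 0.02 and 0.04). The heat shock median went from -0.46 to -0.41 in VSMCs-2 and from -0.59 to -0.53 in VSMCs-1. It shrank from -0.22 to -0.15 in ECs, from -0.24 to -0.13 in Fib-3 and from -0.09 to -0.02 in Fib-2. In Mac and Fib-1, where it was above 0, it was 0.29 and 0.14. A difference in temperature or time of handling stays open, because with 1 pool per group it cannot be told apart from diabetes. It predicted both gene ratios above 1 and both list medians below 0 in each class. Of the 7 classes 5 met this, the exceptions being Mac and Fib-1. The same genes and lists define the pattern, so that count decides nothing. An effect of diabetes was not tested.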

How the results depend on the processing

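Chosen after seeing the data were scaling without haemoglobin genes, removal of the cell holding most UMIs of each gene, the restriction of Mac to marker-assigned macrophages, the shares with barcodes without a class and the rule for genes detected in many cells. Of 246 alternative values of the lead results 230 stayed within their counting interval, 16 were counted as moved and 0 as reversed. Of 1703 other values 1534 stayed, 163 were counted as moved and 6 as reversed. Some values that changed sign were counted as moved, so these counts do not show how many changed direction. The Junb share difference in Mac, a lead result, went from -0.0324 to 14.6 points at 2000 UMIs. The log2 ratio of Fosl1 in VSMCs-2 went from 0.836 to -0.372 with cells thinned to 1000 UMIs. Counts of genes have no such interval and were judged by whether they fell over 1.5-fold. The AP-1 median with partner genes was 0.0202 in all cells, 0.0990 in Mac and 0.264 in Fib-3, where the longer list itself makes the difference. In Mac it was 0.0497 with every cell weighted equally and 0.454 without the 2% of cells with most UMIs. The resident macrophage median in Mac was -0.570 with trimmed mean scaling, -0.352 without mitochondrial and ribosomal protein genes, -0.374 with equal weights and -0.3595 in marker-assigned macrophages, and the inflammatory monocyte median was 0.239 with trimmed means, 0.569 with equal weights and 0.0382 in marker-assigned macrophages. The Fib-2 collagen median was -0.204 without mitochondrial and ribosomal protein genes. The endothelial share difference was -0.732 points with fixed markers and the barcodes without a class together (-3.35 with fixed markers alone), the Mac difference in cells with a Junb UMI was 14.6 points at 2000 UMIs, and of the 50 largest differences named in the main classes 2 were shared with the genes detected in many cells. Reversed were the medians of inflammatory monocyte genes in all cells (0.230), foamy macrophage genes in Mac (0.0732) and RAGE-related genes in VSMCs-1 (-0.0275) with equal weights, calcification genes in Mac in marker-assigned macrophages (-0.3385), and S100a8 and S100a9 in ECs without the top cell (-0.0393 each), which rest on too few remaining UMIs, for S100a9 on a count of 0 set to the floor, to be a measured change of direction. For the others the cause was not tested. The limit of 10% mitochondrial UMIs removed no annotated cell. Its values are among those counted as having stayed, were fixed in advance and say nothing about stability. Doublet removal took out few cells, yet in Mac it moved the contractile median from 1.30 to 0.88 and the calcification median from 0.78 to 0.09, so values it left in place are weak evidence of stability. Every count of list members that the 2-fold size rule moved became lower, as given beside the lists. Without the top cell 15 pairs of named gene and class had too few UMIs for a ratio, and the alternatives planned for normalized values did not apply because the files hold counts. Depth limits the shallow classes: in simulated data a 2-fold change was recovered in 63.9% of genes in Fib-1 and a 1.5-fold change in 30.6% in VSMCs-1. No paired analysis was possible because each group was 1 pool.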

Other observations

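The gene groups below, and the genes in them, were chosen only after the result was seen, and no further test of an explanation was run on them beyond the alternatives given.

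Cirbp and Rbm3, which encode RNA binding proteins induced by mild cold, had ratios of 2.29 (2.13 to 2.46) and 1.62 (1.56 to 1.69) in all annotated cells. Both lay above 1 in each of the 7 classes, with Cirbp at 2.66 in Fib-2, 2.56 in ECs and 1.38 in Mac and Rbm3 at 1.64, 1.87 and 1.58. Tsc22d3, a gene that glucocorticoids induce, had a ratio of 0.363 (0.339 to 0.388) in all cells and of 0.356 in ECs, 0.369 in Fib-1, 0.382 in Fib-2, 0.608 in VSMCs-2 and 0.821 in Mac. Fkbp5, another glucocorticoid-induced gene, had a ratio of 0.560 in all cells, while Klf9 at 1.07 and Sgk1 at 1.04 were not called. Among circadian clock genes in all cells, Per3 at 0.571 was lower and the activator Arntl at 1.64 was higher. Dbp at 0.786 and Nr1d1 at 0.984 were not called. Ratios in all cells mix class shares with levels within classes. Those of Fkbp5, Klf9, Sgk1 and the clock genes are therefore not read as differences within a class.

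Genes of developing T cells were detected in the Mac class, and it was not settled whether these UMIs come from macrophages, doublets or engulfed cells. A UMI of at least 1 of them was present in 23.7% of control Mac cells (20.1 to 27.7%) and 35.8% of diabetic Mac cells (29.6 to 42.4%), at median depths of 4506 and 4129 UMIs. Among Mac cells that the fixed markers assigned to macrophages the shares were 24.1% and 37.6%. In ECs, which should lack these genes, the shares were 0.546% and 1.75% at 2867 and 3504 UMIs, and in VSMCs-2 4.23% and 5.02% at 5547 and 6523 UMIs. Free RNA gives all classes a like share at like depth, so the lower shares of VSMCs-2 at greater depth argue against free RNA as the whole source in Mac. In the T cell class 10 of 13 control and 57 of 60 diabetic cells had such a UMI. In all annotated cells Dntt, the template-independent polymerase of lymphocyte precursors, had a ratio of 2.08 and Cd8a of 2.29. Both ratios carry the T cell share, 0.425% of annotated control and 2.38% of annotated diabetic cells, and do not describe Mac cells.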
